A study of Schizosaccharomyces pombe with 12 samples.

How the data were processed

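The series holds ribosome footprints and total RNA of fission yeast cells in mid-log growth, wild type and delta4dus, with 3 libraries per genotype and assay (12 libraries). Per the labels, one part of each harvest was frozen for total RNA and the rest was lysed and digested with RNase I, and monosome-protected fragments of 28 to 32 nt were gel-purified. The same protocol text names a stranded library kit for the protected fragments; it names no separate kit for total RNA. The authors deposited a table of raw read counts per transcript for each assay, and their notes name Trimmomatic 0.36, Bowtie2 2.4, HISAT2 and featureCounts on the ASM294v2 build, with no strand setting. The counts are whole numbers and were used as deposited, with no earlier normalization. The authors' deposited comparison table gives log2 fold changes of total RNA, footprints and their ratio, and log2 ratios per genotype, per the file headers, with no tool or scaling stated. The authors' p-values and adjusted p-values were used as deposited; the headers do not say what they test or how they were adjusted, and they were taken to be those of the change in translational efficiency.

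The 12 count columns were mapped to samples by genotype and letter, with 0 columns left over. The totals run from 601969 to 2591755 counts per footprint library and from 1886954 to 2199320 counts per total RNA library. A floor of 3 counts per library was used for values of 0, and it covers counting error only. Both tables have 5136 rows, of which 5107 matched a gene of the ASM294v3 reference by systematic ID (5103 protein-coding, 4 pseudogenes) and 29 did not. The reference was used for names, strands, coding lengths and neighbours only. No pair of libraries had counts as close as sampling alone: chi-square per degree of freedom, over genes with at least 20 counts, was 1.45 to 1.66 between footprint replicates and 1.75 to 4.57 between total RNA replicates.

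Each assay was compared between genotypes, 3 against 3, with edgeR 4.0.16 (quasi-likelihood, TMM, default filterByExpr, two-sided) in R 4.3.3, and p-values were adjusted over all genes tested (Benjamini-Hochberg, threshold 0.05). Translational efficiency was tested as the genotype by assay interaction over the 12 libraries, with TMM within each assay and genes that passed the filter in both assays. A culture here means the footprint and total RNA libraries of the same genotype and letter, a pairing assumed from the letters. The values of translational efficiency per culture used a prior count of 2. Gene lists with at least 5 tested genes were tested with camera in limma 3.58.1 (inter-gene correlation 0.01, Benjamini-Hochberg over the lists of a comparison), and again with an estimated correlation and with fry. DESeq2 1.42.0 was used as an alternative. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for overlaps, correlations and plots.

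The tests between genotypes, the gene lists, the naming rule and all alternatives but the thinning below were fixed before the data were examined, while the comparisons with matched genes, the scaling comparison and the total RNA level of the rows with most footprints were chosen after. Named genes were the dus genes and nda2, the 12 largest rises and 12 largest falls per comparison, and up to 3 called members of each list with the smallest p. The rises and falls were taken from genes with an adjusted p under 0.05, a mean of at least 20 counts and no overlap between the genotypes' libraries, without the deleted genes. The lists were the deleted dus genes, their chromosomal neighbours, strain marker, mating-type and pheromone, early meiosis, middle meiosis and sporulation, nitrogen starvation, core stress response, chaperone, cytoplasmic ribosomal protein, ribosome biogenesis, translation factor, cytoplasmic tRNA ligase, other tRNA modification, amino acid biosynthesis, purine and pyrimidine, tubulin and microtubule, actin cytoskeleton, chromosome segregation, histone, glycolysis and fermentation, glucose-repressed, nuclear respiratory chain, mitochondrial genome, proteasome, iron-responsive, phosphate and thiamine, Tf2 retrotransposon, fatty acid and sterol, and sulfur and redox genes. No gene of the mitochondrial genome list matched a row by name, so that list was not analysed here. Some symbols named other genes than intended. Among them, hrs1 in the early meiosis list is a histidine tRNA ligase and ssp1 in the chaperone list is a protein kinase. Mod5, taken by pattern into the other tRNA modification list, is annotated as a Tea1-anchoring protein.

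For the strand relation, the partner signal of a row was the footprint density (mean CPM of the 6 footprint libraries per kb of coding length) of each gene overlapping its exons on the opposite strand, times the overlap, summed over such genes. For fold changes, rows were also taken with at least 90% of the signal from one partner and at least 50 CPM. For matched comparisons, each list gene was set beside the median of 10 genes of nearest coding length and footprint level, from outside the list and outside the chaperone and ribosomal protein lists, and the interval holds 95% of 10000 resamplings of the list's genes. For scaling, which moves all genes alike, the list median was set against the median of all other genes tested, with the same kind of interval. These intervals cover the spread among a list's genes, drawn as if independent, and not the spread between libraries.

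Alternatives covered DESeq2, DESeq2 size factors, no filter, a mean of 50 counts, protein-coding genes only, an absolute log2 fold change of at least 1, the replicate letter or the culture as a block, all 12 libraries in one fit, limma-voom with the culture as a random effect, and leaving out each library or culture. Thinning of the footprint libraries to 601969 reads was chosen after seeing the data. The pairing of genotypes by letter was checked with residual correlations over well-covered genes. Same-letter values were 0.0734, 0.0555 and 0.0159 in footprints and 0.0183, -0.146 and -0.489 in total RNA. Values between letters ran from -0.0563 to 0.00346 in footprints and from -0.315 to 0.365 in total RNA. Same letters were thus closer in footprints, by small values, and not in total RNA. The labels state no pairing of genotypes, so letters were used between genotypes only as an alternative block. Between assays, values ran from -0.0365 to 0.0704 for the same letter and from -0.102 to 0.0578 otherwise.

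The tests were run on simulated data before use. With 3 libraries per group at these depths, genes changed 1.5-fold, 2-fold and 4-fold were recovered in 55.1%, 85.9% and 99.5% of cases in footprints, 42.1%, 85.6% and 100% in total RNA and 10.3%, 57.8% and 99.5% in translational efficiency. Of the calls, in the same order, 6.03%, 6.08% and 3.86% were false in footprints and 8.79%, 4.57% and 3.85% in total RNA. In translational efficiency, 4.76%, 9.02% and 3.05% were false. The changed genes were drawn at random, yet camera called 1 list in footprints at 1.5-fold and at 2-fold, and 1 in total RNA at 2-fold. The strand statistic gave a rho with the partner of 0.00203 for simulated reads of the row's own strand and 0.914 for reads of the opposite strand. The matched comparison returned a median difference of 0.0119 where none was added and of 0.395 where 0.4 was added.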

Results

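Ribosome footprints and total RNA were sequenced from fission yeast (Schizosaccharomyces pombe) in mid-log growth, in wild type and in delta4dus, a strain read from its name as lacking the 4 dihydrouridine synthase genes dus1 to dus4. These enzymes reduce uridine to dihydrouridine in RNA. Each genotype had 3 footprint libraries and 3 total RNA libraries, lettered A to C, which makes 12 libraries. The footprints were monosome-protected fragments of 28 to 32 nt. The wild-type footprint libraries held 1725344, 601969 and 750887 counts in replicates A, B and C, and the delta4dus footprint libraries held 1747608, 1994277 and 2591755 counts. The total RNA libraries were closer in depth, with 2033890, 1986580 and 1900650 counts in wild type and 2199320, 1911782 and 1886954 counts in delta4dus. Wild-type footprints were therefore the shallowest group, and replicate B was the shallowest library. Within a group, gene counts of any pair of libraries had a Spearman rho across genes of 0.968 to 0.988 for footprints and of 0.969 to 0.98 for total RNA. The labels do not state that the letters are separate cultures, so the p-values may measure technical spread in place of the spread between cultures. Values per gene are CPM (counts scaled to TMM-adjusted library sizes) as mean ± SD with n = 3, and fold changes are log2 of delta4dus over wild type. Adjusted p-values are Benjamini-Hochberg values from edgeR quasi-likelihood tests.

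The deleted genes were compared first, in every library, to see whether the genotype labels fit the counts. In footprints, all 4 dus genes fell, dus1 and dus3 to almost nothing. Dus1 (SPBC36B7.04, chromosome II, 2389577 to 2390997 in the ASM294v3 reference) had 40.2 ± 5.22 CPM in wild type and 0 counts in the 3 delta4dus libraries. At a floor of 3 counts per library, 1.57 CPM on average, dus1 footprints were at least 25.6-fold lower, a bound for counting error only. Dus3 (SPAC16.04, chromosome I, 4429636 to 4431741) had 78.8 ± 3.49 CPM in wild type and 2 counts in delta4dus, 0.401% of the wild-type level (log2 fold change -7.56, SE 0.36, adjusted p = 4.29e-30). Its delta4dus counts lie under the same floor, so this percentage and this fold are not exact. Dus2 (SPBC1709.06, chromosome II, 1108708 to 1110598) kept 14 counts, 12.6% of the wild-type level, going from 20.1 ± 6.16 to 2.54 ± 1.58 CPM (-3.11, SE 0.385, adjusted p = 2.35e-10). Dus4 (SPCC777.15, chromosome III, 1624649 to 1626267) kept 35 counts, 35.7% of the wild-type level, going from 15.5 ± 3.33 to 5.54 ± 3.12 CPM (-1.34, SE 0.351, adjusted p = 0.00189). All 3 delta4dus libraries lay below all 3 wild-type libraries for each of the 4 genes. The counts left for dus2 and dus4 do not show a full loss of these genes, and how the loci were deleted is not given.

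In the total RNA table, 3 of the 4 rows of the deleted genes were lower, by less than in footprints, and the dus1 row was higher. Total RNA rows followed genes on the opposite strand, as given below, so these values are not read as mRNA of the deleted genes. On that strand the neighbour pib1 overlaps the dus1 row and the neighbour ekc1 overlaps the dus4 row (281 bp). The dus3 row fell from 25.2 ± 0.743 to 4.87 ± 2.12 CPM (log2 fold change -2.32, adjusted p = 4.19e-05), and the dus2 row fell from 15.8 ± 0.397 to 9.51 ± 0.594 CPM (-0.72, adjusted p = 0.0274). The dus1 row rose from 24.1 ± 1.55 to 35.3 ± 3.04 CPM (0.55, adjusted p = 0.0243). The dus2 call was lost with DESeq2 (adjusted p = 0.0915), with the replicate letter as a block (0.0634) and without any library but wild-type replicate C (0.0589 to 0.0794). The dus1 call was lost with DESeq2 (adjusted p = 0.132), with the block (0.0569) and without wild-type replicate A (0.0715) or C (0.0774) or delta4dus replicate A (0.0755) or B (0.11). The dus4 row changed by -0.43 (adjusted p = 0.0307), a call that was lost without wild-type replicate A (adjusted p = 0.0894), without delta4dus replicate A (0.0723) or C (0.0993), with a mean of 50 counts required (0.0512) and with the replicate letter as a block (0.0675). The genes on either side of the deleted loci, which can carry effects of the deletion itself, were a list fixed before the data were examined. In footprints, 4 of these 8 neighbours rose, none fell and 4 did not pass, with the same 4 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.194). The risers were pib1 (1.18), ura2 (0.68), sfp1 (0.53) and sks2 (0.24), and the sfp1 call was lost after thinning to equal depth, an alternative chosen after seeing the data (adjusted p = 0.0962). Footprints of prp4 and sec63 changed by -0.26 and 0.03 and did not pass. In total RNA, in contrast, the rows of sec63 and prp4 had the largest rises by the naming rule, from 2.71 ± 0.927 to 186 ± 5.88 CPM (6.06) and from 41.4 ± 4.18 to 2128 ± 78.3 CPM (5.68).

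Footprints were compared between genotypes to see which genes had more or fewer ribosomes in delta4dus. Chaperone genes had the largest mean rise of the lists (0.82), while the histone list had a higher median (0.51) and the mating (-0.90) and glucose-repressed (-0.88) lists had means further from 0. Footprints of the disaggregases hsp104 and hsp78, the Hsp70 genes ssa1 and ssa2, hsp90 and its co-chaperone sti1 were 3.21- to 5.52-fold higher in delta4dus. Among single genes, urg1, urg2, uck2, hem13, ght5, ght8, ght1 and mfm2 fell. Of the 138 ribosomal protein genes, 137 rose (list median 0.39). Of 4505 genes tested, 654 were higher and 635 lower (28.6%), and 90 and 153 of these changed at least 2-fold. In 1749 genes (38.8%) the 3 libraries of one genotype all lay above the 3 of the other, where chance gives 10%. With DESeq2, 335 genes were lower in place of 635.

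Of 30 chaperone genes tested in footprints, 17 rose, 1 fell and 12 did not pass (median log2 fold change 0.40). Among those that did not pass were cct1 (0.13), cct6 (0.11), cct2 (0.09), cct4 (-0.01) and cdc37 (0.22), so the rise did not cover the list as a whole. Adjusted over the list alone, 19 rose and 1 fell. The list passed camera (adjusted p = 8.18e-48) and also with an estimated correlation (adjusted p = 0.0421). Hsp104, which pulls proteins out of aggregates, rose from 79.0 ± 10.3 to 382 ± 6.11 CPM (2.34, SE 0.0904, adjusted p = 1.61e-35), and its mitochondrial relative hsp78 rose from 25.3 ± 2.81 to 134 ± 7.79 CPM (2.46). Sti1, which hands clients from Hsp70 to Hsp90, rose from 315 ± 19.1 to 1395 ± 26.1 CPM (2.17). The abundant chaperones hsp90 and ssa2 rose from 3012 ± 135 to 9691 ± 285 CPM (1.68) and from 3222 ± 258 to 11080 ± 197 CPM (1.78), and ssa1 rose by 2.10. Co-chaperone genes outside the list also stood among the 12 largest rises: the Hsp70 nucleotide exchange factor fes1 (2.01) and the cyclophilin wis2 (2.19). Psi1, a J-domain co-chaperone on this list and on the stress list, rose by 2.18. The 1 gene of the list that fell was the protein kinase gene ssp1 (-0.42), which is not a chaperone.

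**Figure D1:**
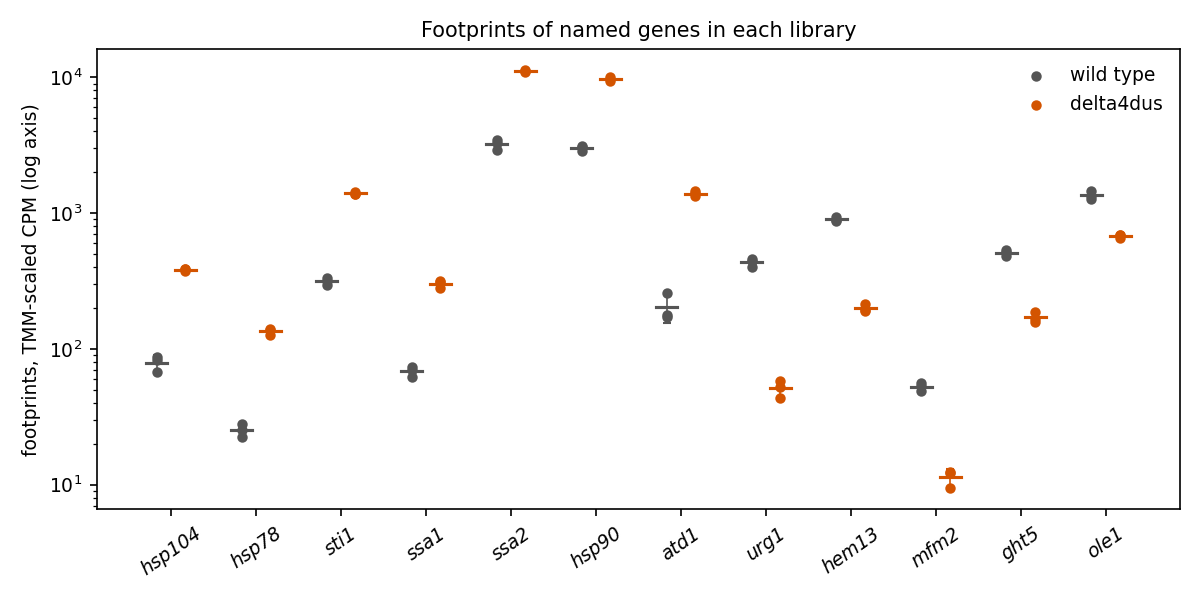
Footprint levels of 12 named genes in each library, in TMM-scaled CPM on a log axis; points are libraries, lines are means and error bars are SD (n = 3 per genotype). For hsp104 the delta4dus mean is 382 CPM against 79.0 CPM in wild type, and for urg1 it is 51.2 CPM against 435 CPM.

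Stress and redox genes moved in both directions. Of 24 core stress response genes, 13 rose, 6 fell and 5 did not pass, and 13 rose and 7 fell when adjusted over the list alone (median 0.31, camera adjusted p = 5.72e-05, adjusted p = 0.112 with an estimated correlation). The cytosolic thioredoxin trx1 rose from 510 ± 25.4 to 1331 ± 30.6 CPM (1.39) and tps1, which makes trehalose phosphate, rose by 1.32. The catalase ctt1, a standard marker of oxidative stress, fell by 0.53 on the log2 scale. Of 19 sulfur and redox genes, 8 rose, 2 fell and 9 did not pass, and 9 rose and 2 fell when adjusted over the list alone (median 0.09, camera adjusted p = 0.0281, adjusted p = 0.147 with an estimated correlation). That list was also lost with footprint libraries thinned to equal depth, an alternative chosen after seeing the data (adjusted p = 0.104). The thioredoxin peroxidase tpx1 rose by 0.44. Against other genes of matched coding length and level, a comparison chosen after seeing the data, the stress list median differed by 0.266 (95% interval -0.136 to 0.633) and the sulfur and redox median by -0.0221 (-0.181 to 0.191). The largest rise by the naming rule was that of atd1, an aldehyde dehydrogenase, from 202 ± 46.8 to 1393 ± 54.3 CPM (2.85, SE 0.0712, adjusted p = 3.45e-47). Pmp20, a thioredoxin-related protein, rose by 2.10 and the copper transporter subunit ctr4 by 1.91. SPCC417.16, annotated as a subunit of an NADH:ubiquinone reductase complex, rose by 2.76, and SPBPB2B2.05, a glutamine amidotransferase family gene, by 2.09.

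The largest falls by the naming rule were in genes of varied annotation. Urg1, a uracil-regulated gene annotated as a GTP cyclohydrolase II, fell from 435 ± 33.2 to 51.2 ± 7.04 CPM (-3.12, SE 0.0907, adjusted p = 1.88e-43). Urg2 and uck2, both annotated as uracil phosphoribosyltransferases, changed by -2.39 and -2.85. The annotated spermidine-family transporter mfs3 changed by -2.93, the transcription factor cbf12 by -2.61 and the acyl-CoA thioesterase the4 by -2.19. Hem13, the coproporphyrinogen oxidase of haem synthesis, fell from 901 ± 28.7 to 199 ± 13.4 CPM (-2.17). The uncharacterised genes SPBC1271.08c and SPAPB24D3.07c changed by -2.23 and -2.15, and fsh2, a serine hydrolase-like gene, by -1.87. SPMIT.04, a mitochondrial row by its ID and with no match in the reference, changed by -2.03.

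Several sugar transporter and lipid genes fell. Of 10 glucose-repressed genes, none rose, 6 fell and 4 did not pass, with the same counts when adjusted over the list alone (median -0.93, camera adjusted p = 3.74e-07, adjusted p = 0.112 with an estimated correlation). The hexose transporter genes ght5, ght8 and ght1, members of a family of related sequences, fell from 510 ± 23.9 to 171 ± 14.9 CPM (-1.58), from 702 ± 37.8 to 294 ± 11.7 CPM (-1.24) and by 1.10 on the log2 scale. Of 29 fatty acid and sterol genes, 2 rose, 11 fell and 16 did not pass, and 2 rose and 12 fell when adjusted over the list alone (median -0.17, camera adjusted p = 0.000339, adjusted p = 0.112 with an estimated correlation). Ole1, the fatty acid desaturase, fell from 1355 ± 94.8 to 678 ± 17.8 CPM (-0.99). The sterol enzymes erg31 and erg1 changed by -1.81 and -0.96. Of 10 phosphate and thiamine genes, 2 fell and 8 did not pass, with 2 falling when adjusted over the list alone (median -0.22, camera adjusted p = 0.00713, adjusted p = 0.112 with an estimated correlation). The acid phosphatase pho1 fell from 479 ± 45.7 to 161 ± 6.9 CPM (-1.61) and the phosphate transporter pho84 by 0.76 on the log2 scale. Against other genes of matched coding length and level, a comparison chosen after seeing the data, list medians differed by -0.966 (95% interval -1.37 to -0.128) for glucose-repressed, -0.153 (-0.278 to 0.0187) for fatty acid and sterol and -0.184 (-0.752 to 0.126) for phosphate and thiamine genes.

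Several mating and starvation genes fell. Of 11 mating-type and pheromone genes tested, 7 fell and 4 did not pass, and 10 fell when adjusted over the list alone (median -0.86, camera adjusted p = 0.00635, adjusted p = 0.112 with an estimated correlation). The call was also lost after thinning to equal depth (adjusted p = 0.0603). The M-factor precursor mfm2 fell from 52.5 ± 3.41 to 11.4 ± 1.73 CPM (-2.15), the M-factor transporter mam1 changed by -1.94 and the M-specific transcription factor mat1-Mc by -0.87. Of 19 nitrogen starvation genes, 6 fell and 13 did not pass, and 7 fell when adjusted over the list alone (median -0.25, camera adjusted p = 0.00904, adjusted p = 0.112 with an estimated correlation). The amino acid transporter isp5 changed by -3.75, the oligopeptide transporter isp4 by -1.84 and the ammonium transporter amt1 by -1.06. Of 13 Tf2 retrotransposon genes, 9 fell and 4 did not pass, and 10 fell when adjusted over the list alone (median -0.57, camera adjusted p = 0.00904, adjusted p = 0.345 with an estimated correlation). Tf2 copies are near identical, so their separate values are uncertain. Against other genes of matched coding length and level, a comparison chosen after seeing the data, list medians differed by -0.807 (95% interval -1.06 to -0.471) for mating, -0.163 (-0.5 to -0.00478) for nitrogen starvation and -0.0933 (-0.244 to 0.0404) for Tf2 genes.

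The meiotic and chromosome segregation lists, which the study's title concerns, did not pass in these mid-log footprints. Of 6 early meiosis genes tested, 2 fell and 4 did not pass, with 2 falling when adjusted over the list alone (camera adjusted p = 0.453). The median of this list was 0.02 and its mean -0.63, with the camera direction down. Its called members were dhc1, the dynein heavy chain of meiotic nuclear movement (-3.29), and mei2, the RNA-binding regulator of meiosis (-1.06). Mei2 lost its call without wild-type replicate A (adjusted p = 0.0721), without delta4dus replicate C (0.0878) and with DESeq2 (0.0659). Of 39 chromosome segregation genes, 2 rose, 2 fell and 35 did not pass, with the same 2 and 2 counts when adjusted over the list alone (median -0.04, camera adjusted p = 0.848). Slp1, the activator of the anaphase-promoting complex, rose from 22.6 ± 8.0 to 54.6 ± 6.74 CPM (1.44). Dad1 of the DASH complex changed by 1.20, which did not pass without wild-type replicate A (adjusted p = 0.127). The alpha tubulin gene nda2 had 330 ± 20.8 CPM in wild type and 295 ± 7.8 CPM in delta4dus (-0.14, SE 0.0685, adjusted p = 0.111). The 3 delta4dus libraries lay below the 3 wild-type libraries for nda2. The change passed with a mean of 50 counts required (-0.19, adjusted p = 0.0127) and after thinning, chosen after seeing the data (-0.28, adjusted p = 0.0283).

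Of 138 cytoplasmic ribosomal protein genes, 137 rose, none fell and 1 did not pass (median 0.39), and 138 rose when adjusted over the list alone. The list passed camera (adjusted p = 3.17e-59) and not with an estimated correlation (adjusted p = 0.112). Rpl2002, rpl2001 and rpl2701 rose by 0.70, 0.61 and 0.57, and pairs of ribosomal protein genes are near identical, so single values are uncertain. Fold changes followed coding length and footprint level: across 4490 genes they had a Spearman rho of -0.343 with coding length and of 0.226 with footprint level. Without chaperone and ribosomal protein genes, the median was 0.13 in the shortest 10% of genes and -0.31 in the longest 10%. In the matched comparison, chosen after seeing the data, ribosomal protein genes exceeded other genes matched on both by 0.0313 (95% interval 0.0121 to 0.0467), although the matched genes had a lower median level (993 CPM against 2030 CPM). Chaperones exceeded their matched genes by 0.341 (0.127 to 1.03).

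Of 39 translation factor genes, 16 rose, 2 fell and 21 did not pass, and 16 rose and 3 fell when adjusted over the list alone (median 0.12, camera adjusted p = 0.00713, adjusted p = 0.215 with an estimated correlation). The eIF5A gene tif51 rose by 0.83 and the elongation factor gene tef5 by 0.46. Translation factor genes exceeded their matched genes by 0.0168 (95% interval -0.062 to 0.0662), and tRNA ligase genes by 0.0842 (0.0144 to 0.135). Of 17 cytoplasmic tRNA ligase genes, 7 rose and 10 did not pass, with 7 rising when adjusted over the list alone (median 0.12, camera adjusted p = 0.0411, adjusted p = 0.346 with an estimated correlation). The lysine ligase krs1 rose by 0.39. The tRNA ligase call was also lost without delta4dus replicate A (adjusted p = 0.0678) and after thinning (0.161). Of 10 histone genes, which include near-identical copies, 8 rose and 2 did not pass, and 9 rose when adjusted over the list alone (median 0.51, camera adjusted p = 7.33e-08, adjusted p = 0.147 with an estimated correlation). The histone genes hta1 and hhf1 rose by 0.63 and 0.60. Histone genes exceeded their matched genes by 0.209 (95% interval 0.0472 to 0.31).

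Of 57 nuclear respiratory chain genes, 27 rose, 3 fell and 27 did not pass, with the same counts when adjusted over the list alone (median 0.24, camera adjusted p = 0.00713, adjusted p = 0.112 with an estimated correlation). Qcr8 and rip1 of the cytochrome bc1 complex rose by 0.70 and 0.60, and cytochrome c (cyc1) by 0.42. Their list median exceeded that of matched genes by 0.0842 (95% interval -0.0412 to 0.146). Of 15 glycolysis and fermentation genes, 8 rose, 1 fell and 6 did not pass, and 10 rose and 1 fell when adjusted over the list alone (median 0.13, camera adjusted p = 0.00713, adjusted p = 0.565 with an estimated correlation). Gpm1 and pgk1 rose by 0.53 and 0.48, while the alcohol dehydrogenase adh4 fell by 0.98 on the log2 scale. The median of the glycolysis list lay -0.0585 from that of matched genes (95% interval -0.132 to 0.0525). Its matched genes had a far lower median level (990 CPM against 8490 CPM), so level was not matched for this list. Of 37 proteasome genes, 13 rose and 24 did not pass, with 13 rising when adjusted over the list alone (median 0.15, camera adjusted p = 0.0369, adjusted p = 0.345 with an estimated correlation). Rpt6 and pre3 rose by 0.42 and 0.40. Proteasome genes exceeded their matched genes by 0.0983 (95% interval 0.00342 to 0.182). The proteasome call was lost without wild-type replicate A (adjusted p = 0.0567) and after thinning (0.218).

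**Figure D2:**
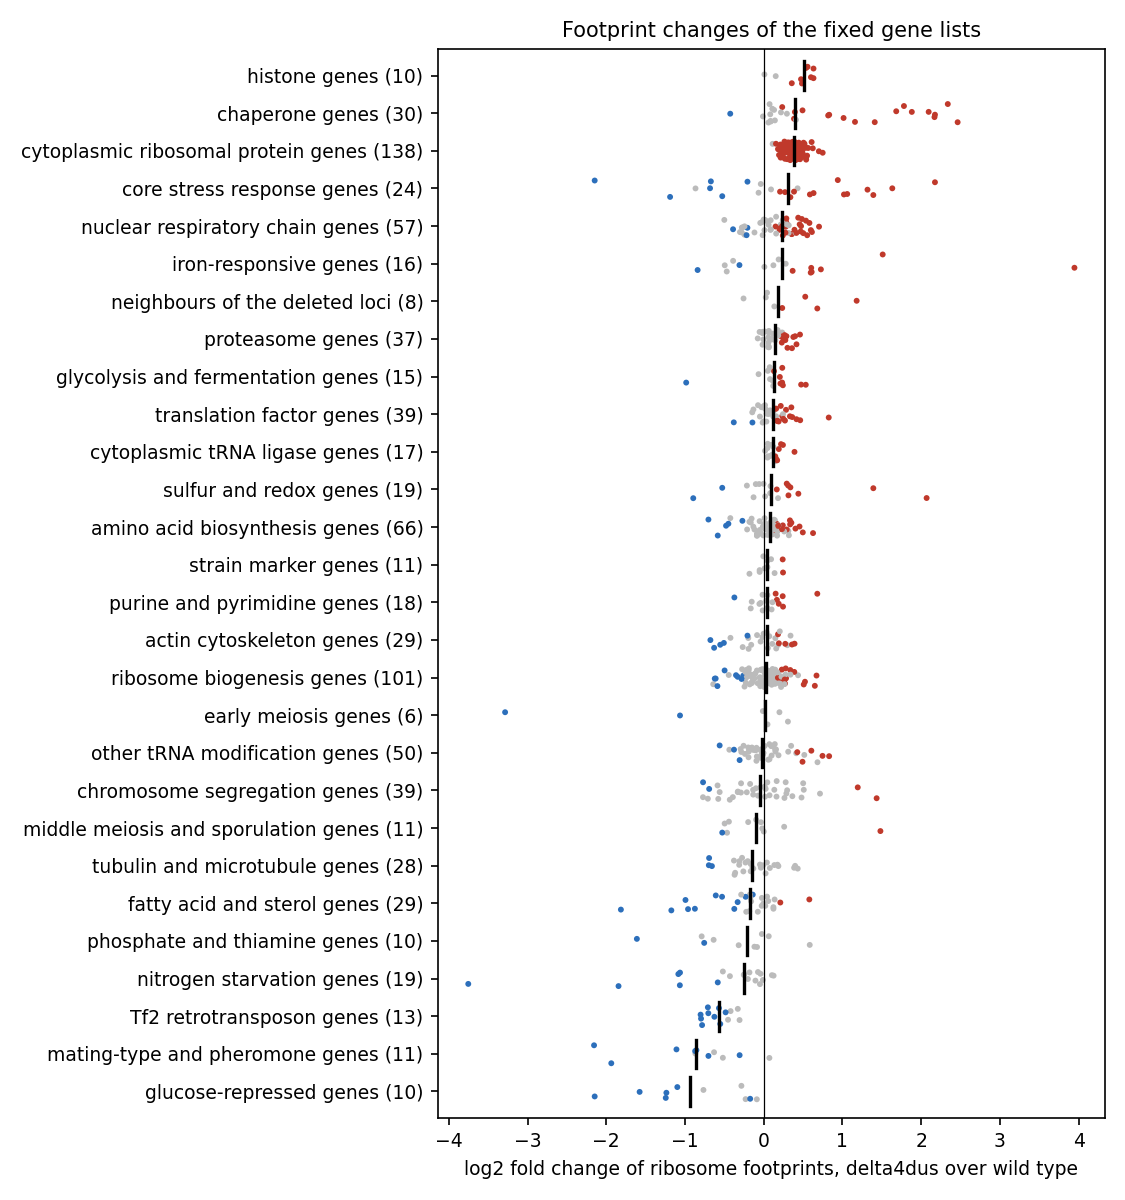
Log2 fold change of ribosome footprints, delta4dus over wild type, for every tested member of the fixed gene lists (number tested in brackets); red points rose, blue points fell, grey points did not pass, and black bars are list medians. The chaperone median is 0.40 with members reaching 2.46, while the ribosomal protein genes lie close together around 0.39.

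In all, 16 of 28 gene lists passed camera in footprints, and with an estimated correlation only the chaperones did. The wild-type footprint libraries were shallower, and thinning every footprint library to 601969 reads left 431 genes higher and 361 lower of those then tested.

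Total RNA was compared to see which mRNAs differed in abundance, but its counts did not follow the footprints of the same genes. Across 5136 genes, total RNA and footprint levels had a Spearman rho of -0.214. Act1 (actin) had 3127 CPM of footprints and 7.75 CPM of total RNA in wild type, and the alpha tubulin gene nda2 had 8 to 14 total RNA counts in each library against 212 to 705 footprint counts. The 100 rows with most footprints had a median total RNA level of 4.71 CPM, against 14.5 CPM for all rows. Total RNA rows instead followed the footprints of genes on the opposite strand. In the 1919 rows whose exons overlap another gene on the opposite strand, rho was -0.239 with the row's own footprints and 0.695 with the overlap-weighted footprints of the opposite gene. That value ranged from 0.684 to 0.702 between the 6 libraries. Of the 100 rows with most total RNA, 96 had such an overlap, against 37.4% of all rows. The total RNA values below are therefore given by row, and are not read as the mRNA level of the gene that names the row.

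**Figure D3:**
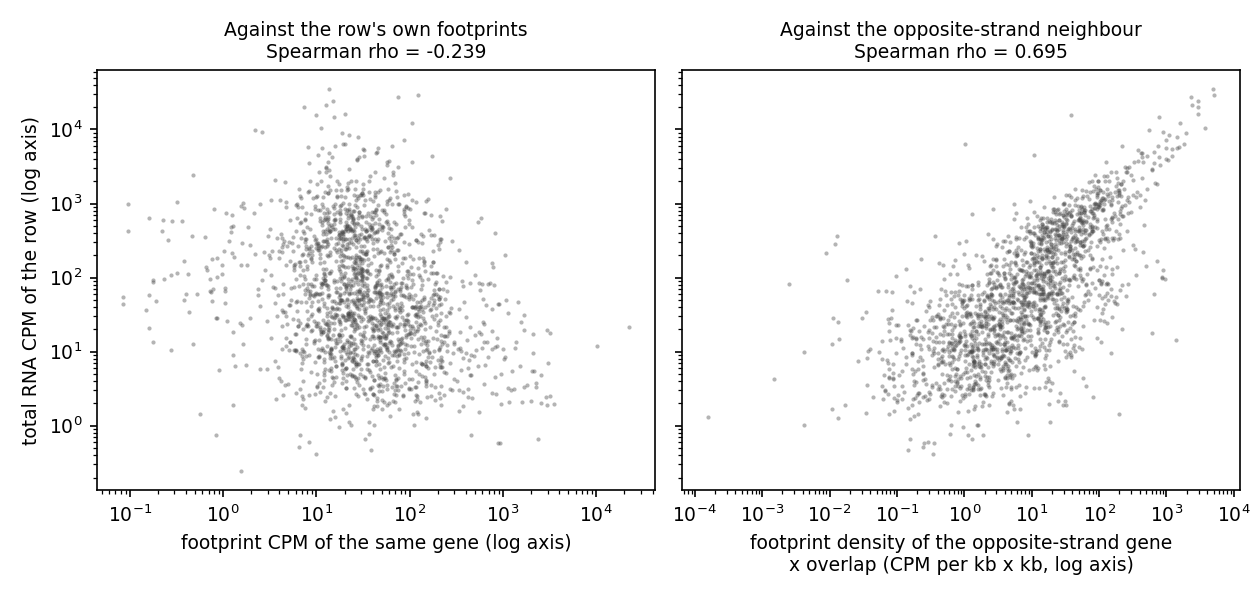
Total RNA CPM of each row that overlaps a gene on the opposite strand, against the footprint CPM of the same gene (left) and against the overlap-weighted footprint density of the opposite-strand gene (right), log axes, values above 0 shown. Spearman rho across rows is -0.239 on the left and 0.695 on the right.

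The largest changes in total RNA lay next to deleted genes or were single rows. Besides sec63 and prp4, the row of pib1, which overlaps dus1 on the opposite strand, rose from 13.4 ± 0.613 to 68.7 ± 1.84 CPM (2.35). The row of rmt1, an arginine methyltransferase gene, rose by 2.75, those of the kinase genes lsk1 and hri1 by 1.87 and 1.67, and that of the nucleoporin gene nup211 by 1.82. The rows of the transcription factor gene phx1 and the RNA-binding protein gene puf5 rose by 1.80 and 1.77. The row of med15, a Mediator subunit gene, fell from 299 ± 14.5 to 8.21 ± 1.37 CPM (-5.16, SE 0.128, adjusted p = 3.05e-13), while med15 footprints changed by -0.21 (adjusted p = 0.33). The rows of SPBC354.11c and php2 fell from 762 ± 86.9 to 158 ± 4.69 CPM (-2.26) and from 1230 ± 96.1 to 361 ± 25.04 CPM (-1.77). The rows of gto2, pho84, tgd1, nep2 and pmd1 changed by -1.54, -1.18, -1.17, -1.15 and -1.12.

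Of 3791 rows tested in total RNA, 475 were higher and 394 lower (22.9%), and 112 and 19 of these changed at least 2-fold. In 1405 rows (37.1%) the genotypes did not overlap, where chance gives 10%. The neighbours of the deleted loci were the only list of 28 that passed: 4 of 7 rows rose, none fell and 3 did not pass, with 4 rising when adjusted over the list alone (median 1.42, camera adjusted p = 8.05e-40, adjusted p = 0.0143 with an estimated correlation). Of 22 chaperone rows, 3 rose and 19 did not pass, with 3 rising when adjusted over the list alone (median 0.17, camera adjusted p = 0.984). Hsp104 was one of them, from 7.25 to 16.9 CPM (1.21), a call lost without delta4dus replicate A (adjusted p = 0.0526) or C (0.0547). Of 36 ribosomal protein rows, 1 rose, 3 fell and 32 did not pass, and 1 rose and 2 fell when adjusted over the list alone (median -0.00376, camera adjusted p = 0.984). The counts were 287 and 236 without wild-type replicate A, 262 and 187 without delta4dus replicate A, and 294 and 199 without delta4dus replicate B. The balance of directions was not stable: DESeq2 size factors gave 376 rows higher and 527 lower, DESeq2 gave 229 and 420, and leaving out wild-type replicate C gave 434 and 478.

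Translational efficiency, footprints over total RNA, was compared between genotypes to see whether genes gained or lost ribosomes beyond their RNA. Because the denominator is the total RNA row, these ratios carry the strand relation given above and are not read as ribosomes per mRNA. Of the genes named for their footprints, atd1 rose by 2.84, fes1 by 2.44, hsp78 by 2.19, the siderophore transporter str1 by 2.03, ssa2 by 1.86, ctr4 by 1.85 and ssa1 by 1.49. The largest rise and the 2 largest falls by the naming rule, which leaves out the deleted genes, were in rows with the largest total RNA changes: med15 rose by 4.98, and sec63 and prp4 changed by -6.00 and -5.90. Other falls were isp5 (-3.98), SPBC1271.08c (-3.82), dhc1 (-3.75), urg1 (-3.42), uck2 (-3.25), mfs3 (-2.91) and cbf12 (-2.88). The elongation factor gene tef102, which has near-identical copies, had a change of 2.38 that did not pass without wild-type replicate B (0.44, adjusted p = 0.519). Of the dus genes, dus1 (fitted -9.87, with 0 footprint counts in delta4dus, so no bound), dus3 (-5.29) and dus2 (-2.38) fell, and dus4 did not pass (-0.86, adjusted p = 0.0974). Dus4 passed without delta4dus replicate C (-1.63, adjusted p = 0.00673) and with limma-voom (-0.98, adjusted p = 0.0493).

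Of 3330 genes tested for translational efficiency, 211 were higher and 463 lower (20.2%), and 75 and 275 of these changed at least 2-fold. In 1146 genes (34.4%) the genotypes did not overlap, where chance gives 10%. The direction balance depended on the scaling: 31.3% of the calls were higher with TMM within each assay, 40.8% with DESeq2 size factors in the same test (262 higher and 380 lower) and 48.8% with TMM over all 12 libraries, as the median over all genes moved from -0.15 to -0.07 and -0.02. With DESeq2, which changes the test as well as the scaling, 72.5% were higher (438 higher and 166 lower). The counts fell to 139 higher and 287 lower without wild-type replicate A.

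Of 27 lists tested, 11 passed for translational efficiency, here and below a ratio to total RNA rows and not read as ribosomes per mRNA. Only genes whose total RNA rows also passed the filter were tested, such as 22 of 30 chaperone and 36 of 138 ribosomal protein genes. Chaperones had 8 of 22 genes up and 14 not passed, with 8 up when adjusted over the list alone (median 0.31, camera adjusted p = 3.58e-06, adjusted p = 0.0296 with an estimated correlation). The neighbours of the deleted loci had 3 of 7 genes down and 4 not passed, with 1 up and 3 down when adjusted over the list alone (median -1.14, camera adjusted p = 3.58e-06, adjusted p = 0.0296 with an estimated correlation). The other 9 were lost with an estimated correlation. Ribosomal proteins had 10 of 36 up, 1 down and 25 not passed, with 13 up and 1 down when adjusted over the list alone (median 0.42, camera adjusted p = 4.63e-05, adjusted p = 0.1 with an estimated correlation). Glucose-repressed genes had 6 of 9 down and 3 not passed, with 6 down when adjusted over the list alone (median -0.85, camera adjusted p = 0.00132, adjusted p = 0.1 with an estimated correlation), among them ght8, which fell by 1.21 on the log2 scale. Mating genes had 5 of 7 down and 2 not passed, with 5 down when adjusted over the list alone (median -1.18, camera adjusted p = 0.0261, adjusted p = 0.1 with an estimated correlation). Tf2 genes had 5 of 12 down and 7 not passed, with 10 down when adjusted over the list alone (median -0.82, camera adjusted p = 0.00486, adjusted p = 0.359 with an estimated correlation).

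Translation factors had 4 of 23 up and 19 not passed, with 2 up when adjusted over the list alone (median 0.36, camera adjusted p = 0.00132, adjusted p = 0.0796 with an estimated correlation). Amino acid biosynthesis genes had 11 of 48 up, 1 down and 36 not passed, with 12 up and 1 down when adjusted over the list alone (median 0.13, camera adjusted p = 0.00132, adjusted p = 0.0796 with an estimated correlation), and lys9 rose by 0.73. Proteasome genes had 1 of 23 up, 1 down and 21 not passed, with 1 up when adjusted over the list alone (median 0.33, camera adjusted p = 0.0337, adjusted p = 0.1 with an estimated correlation), and the call was lost without wild-type replicate C (adjusted p = 0.067). Histones had 2 of 5 up and 3 not passed, with 2 up when adjusted over the list alone (median 0.24, camera adjusted p = 0.0482, adjusted p = 0.201 with an estimated correlation). The nuclear respiratory chain had 4 of 34 up, 2 down and 28 not passed, with the same counts when adjusted over the list alone (camera adjusted p = 0.0482, adjusted p = 0.1 with an estimated correlation). Its median was -0.06 while its mean, 0.05, and its test pointed up, and its median changed sign with DESeq2 size factors. With the culture as a block, the histone (adjusted p = 0.0551) and respiratory chain (0.0584) calls were lost. The histone call was also lost without wild-type replicate B (0.126) or C (0.056) or delta4dus replicate A (0.0545), and the respiratory chain call without wild-type replicate A (0.071) or C (0.0917).

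Fold changes in footprints and in total RNA were compared across the 3330 genes tested in both assays. Pearson's r across genes was 0.0201 and Spearman's rho -0.0173, and genes are not independent replicates. Of 160 genes called in both assays, 83 changed in the same direction, and 190 would be called in both if the calls were independent.

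The authors' deposited table gives log2 fold changes in 5136 rows, 4878 of them with an adjusted p, which was taken to be that of translational efficiency. In it, 519 rows were higher and 228 lower at an adjusted p under 0.05. Of the 3330 genes also tested here, 202 were higher in both, 194 lower in both and 0 in opposite directions, out of 671 called by the authors. The balance of directions was the reverse of that here, where 211 were higher and 463 lower, and a correlation across rows cannot show this. The authors' counts cover 4878 rows and those here 3330 genes. For the dus1, dus2, dus3 and dus4 rows, that table gives total RNA changes of 0.291, -0.987, -2.6 and -0.699. Each is lower than here (0.552, -0.72, -2.32 and -0.435). A difference in scaling would shift all rows alike and leave r unchanged, and it was not tested as the cause. The table's fold changes had a Pearson r across rows of 1 with those here in total RNA, 0.996 in footprints and 0.996 in translational efficiency. Given these r values, the strand relation of the total RNA rows applies to that table's mRNA and translational efficiency columns too. For nda2, whose total RNA row holds 8 to 14 counts in each library, the authors' table gives a log2 change of -0.66 in its mRNA column, -0.06 in footprints and 0.60 in translational efficiency (adjusted p = 0.324 in that table).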

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

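Thinning the footprint libraries to equal depth was chosen after seeing the data; the other alternatives were planned, and no named gene or list call turned to the opposite direction. The balance of directions did turn: total RNA had 376 rows higher and 527 lower with DESeq2 size factors and 434 and 478 without wild-type replicate C, and the DESeq2 counts below turn it in total RNA and in translational efficiency. In footprints, where the 2 counts are close, one fit of all 12 libraries gave 533 and 564, and a mean of 50 counts 498 and 499. For footprints, 654 genes were higher and 635 lower; DESeq2 gave 335 lower, a log2 fold change of at least 1 left 90 higher and 153 lower, and thinning, which lowers the depth and the number of genes tested, left 431 higher and 361 lower. With an estimated correlation, 1 list passed in footprints in place of 16, and 2 in translational efficiency in place of 11. For total RNA, 475 rows were higher and 394 lower. DESeq2 gave 229 higher and 420 lower, and a log2 fold change of at least 1 left 112 and 19. The replicate letter as a block left 297 and 197. Fry called 2 lists in total RNA in place of 1, adding chromosome segregation genes (adjusted p = 0.0352). In footprints fry, which does not compare a list with other genes, called 21 lists in place of 16. It added the neighbours of the deleted loci (adjusted p = 0.00646), early meiosis (0.0115), iron-responsive (0.0116), amino acid biosynthesis (0.0174) and tubulin (0.0384) genes. In translational efficiency fry called 15 lists in place of 11. It added tubulin (adjusted p = 0.00264), chromosome segregation (0.0031), nitrogen starvation (0.0049) and fatty acid and sterol (0.0283) genes. Leaving out 1 library gave 262 to 434 rows higher and 187 to 478 lower, with fewer libraries in each fit. For translational efficiency, 211 genes were higher and 463 lower; DESeq2 gave 438 and 166, a mean of 50 counts, which leaves 736 genes to test, gave 89 and 137, and a log2 fold change of at least 1 left 75 and 275. Leaving out 1 culture gave 139 to 205 higher and 287 to 372 lower. Spearman's rho between footprint and total RNA fold changes was 0.00641 over genes called in 1 or both assays, -0.0775 with a mean of 50 counts, and -0.0354 to 0.00444 with 1 culture left out. In the authors' deposited table, a log2 fold change of at least 1 left 222 higher and 136 lower. Where not given here, the cause of a shift was not tested. With the replicate letter as a block, 592 footprint genes were higher and 548 lower, and 177 and 382 in translational efficiency; with the culture as a block, 188 and 436 changed in translational efficiency. Over all alternatives, named genes lost their call 94 times in footprints, 136 times in total RNA and 131 times in translational efficiency, mostly through the fold threshold of 1 and leaving out a library; lists lost their call 21, 0 and 17 times. The deleted genes kept their calls with DESeq2 size factors in both assays, while the total RNA calls of dus1, dus2 and dus4 were lost with the replicate letter as a block and without some libraries, and those of dus1 and dus2 with DESeq2. Shallow wild-type footprint libraries limit what can be called among genes with few footprints.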

Other observations

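The tests of matched coding length and level, those of footprint scaling, the test of translation setting footprints apart from mRNA, and the thinning of footprint libraries were chosen after the result was seen; the other tests were not. Of 16 iron-responsive genes, 7 rose in footprints, 2 fell and 7 did not pass, and 7 rose and 3 fell when adjusted over the list alone, while the list did not pass (median 0.24, camera adjusted p = 0.209). The siderophore transporter str1 rose from 35.8 ± 3.8 to 104 ± 4.58 CPM (1.51), and the iron uptake gene fio1 rose by 0.60. The siderophore transporter str3 rose from 0.586 ± 0.605 to 10.7 ± 1.16 CPM (fitted 3.95). Its wild-type level lay below the floor of 3 counts in each wild-type library (1.74, 4.98 and 4 CPM), so that fold is not exact. Of 101 ribosome biogenesis genes, 13 rose, 8 fell and 80 did not pass, with 10 and 7 when adjusted over the list alone (median 0.03, camera adjusted p = 0.953). The helicase dbp2 fell by 0.59 on the log2 scale and the nucleolar gene brx1 rose by 0.39. Of 66 amino acid biosynthesis genes, 14 rose, 5 fell and 47 did not pass, with 14 and 5 when adjusted over the list alone (median 0.09, camera adjusted p = 0.411). Lys4 and met3 rose by 0.40 and 0.63 and met10 fell by 0.58 on the log2 scale. Of 50 other tRNA modification genes, 5 rose, 3 fell and 42 did not pass, with 2 and 1 when adjusted over the list alone (camera adjusted p = 0.986). Their median, -0.02, changed sign with DESeq2, while the medians of the ribosome biogenesis and strain marker lists changed sign after thinning. The diphthamide gene dph3 rose by 0.75, which did not pass after thinning (adjusted p = 0.0761).

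Of 18 purine and pyrimidine genes, 6 rose, 1 fell and 11 did not pass, with 6 and 1 when adjusted over the list alone (median 0.05, camera adjusted p = 0.576). Ura2, which also neighbours dus3, rose by 0.68 and ade3 fell by 0.37 on the log2 scale. Of 28 tubulin and microtubule genes, 3 fell and 25 did not pass, with 3 when adjusted over the list alone (median -0.15, camera adjusted p = 0.453). The falling genes alp4, alp6 and peg1 (-0.70, -0.69 and -0.66) did not pass with DESeq2 (adjusted p = 0.0901, 0.285 and 0.0792). For alp6 the genotypes' libraries overlapped, and its call was also lost with the replicate letter as a block (0.0876) and without replicate B of wild type (-0.38, adjusted p = 0.222) or of delta4dus (-0.44, adjusted p = 0.12). The peg1 call was also lost without wild-type replicate B (0.0694) or delta4dus replicate C (0.0549). Of 29 actin cytoskeleton genes, 5 rose, 5 fell and 19 did not pass, with 7 and 7 when adjusted over the list alone (median 0.04, mean -0.03, camera adjusted p = 0.848 with the direction up), and act1 rose by 0.27. Of 11 middle meiosis and sporulation genes, 1 rose, 1 fell and 9 did not pass, with 1 and 1 when adjusted over the list alone (median -0.10, camera adjusted p = 0.727). The meiotic septin gene spn7 rose from 5.24 ± 2.71 to 14.5 ± 3.34 CPM (1.48). Of 11 strain marker genes, 2 rose and 9 did not pass, with 2 when adjusted over the list alone (median 0.05, camera adjusted p = 0.727), namely ura5 (0.25) and ade6 (0.24). Both calls were lost with DESeq2 (adjusted p = 0.0511 and 0.0955), in one fit of all 12 libraries (0.0591 and 0.0773), after thinning (0.483 and 0.361) and without wild-type replicate A (0.0873 and 0.27), and ade6 also without delta4dus replicate B (0.0534).

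Total RNA counts did not follow footprints across genes, and the opposite-strand partner gave rho = 0.695 in place of -0.239 for the row's own footprints. That value argues against rows being out of order, which needs a rho near 0 (0.695), and the median of 4.71 CPM in the 100 rows with most footprints argues against translation alone setting footprints apart from mRNA, since these genes need abundant mRNA. Counting of reads on the opposite strand may account for the levels, and it stays open as a hypothesis. Total RNA fold changes followed neither strand: rho was 0.043 with the partner's footprint fold change and 0.0282 with the row's own. The changes in total RNA rows are thus not explained by footprint changes of the partner. With both values near 0, fold changes cannot tell the strands apart. No biological explanation of the levels by genotype was tested.

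Chaperone genes were higher in delta4dus footprints, and the tests argue against footprint depth and against coding length with level as the source. The list's median exceeded that of all other genes by 0.433 (95% interval 0.211 to 1.12). Scaling moves every gene alike and so cannot set a list apart, and this value restates the list's call. After thinning the list's median was 0.383 with a camera adjusted p of 1.28e-41, and above genes of matched coding length and level it was 0.341 (95% interval 0.127 to 1.03). A higher output of the chaperones that rose, 17 of the 30 genes on the list, may therefore be biological, as a hypothesis found and tested on the same data. More mRNA, more translation per mRNA and other differences between the cultures, such as growth or strain background, were not separated here.

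Ribosomal protein genes were also higher in delta4dus footprints, by a median of 0.39. Their list median exceeded that of all other genes by 0.429 (95% interval 0.411 to 0.441). Scaling moves every gene alike and so cannot set a list apart, and this value also restates the list's call. The trend of fold changes with coding length and footprint level may account for most of the change, since the list exceeded matched genes by 0.0313. The matched genes had fewer footprints than the list, so the match on level is incomplete. Whether the trend with coding length comes from the libraries or from the cells stays open.

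In rows of at least 50 total RNA CPM opposite a ribosomal protein gene with at least 90% of the partner signal, which by the relation above may hold its reads (rho = 0.695 across rows), 19 of 25 rows were lower in total RNA and 0 higher, with a median of -0.27 against a median of 0.37 in the genes' footprints. In 8 rows opposite genes of the chaperone list, the kinase gene ssp1 among them, 5 were lower and 0 higher (median -0.23, against 0.12 in footprints). The 5 lower rows lay opposite hsp10, whose footprints rose (1.015), and cct1, cct2, cct4 and cct6, whose footprint changes did not pass. Of all 802 rows chosen in this way, 254 were lower and 26 higher (median -0.13), and rows opposite the other lists varied, with 2 of 2 higher for histones and 0 of 6 called for chromosome segregation. Whether these shares differ was not tested. Total RNA fold changes had a rho of -0.316 with total RNA level across 3778 genes.

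The 6 libraries of an assay, or the 6 cultures for translational efficiency, can be split 3 against 3 in 10 ways, too few for a share under 0.05. With edgeR, the real split called 1289 genes in footprints, 869 in total RNA and 674 in translational efficiency, and the highest other split called 0 in each, so that 1 of the 10 splits, the real one, reached its count. Every other split puts both genotypes in each group, so a difference between genotypes widens the spread within groups and lowers the calls. The counts of the other splits are thus no measure of calls by chance. For gene lists the real split called 16 in footprints, 1 in total RNA and 11 in translational efficiency, and the highest other split called 9, 2 and 3, so that 1, 4 and 1 of the 10 splits called as many.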
